A study of Homo sapiens with 6 samples.

How the data were processed

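The samples were 6 RNA-seq libraries of the Jurkat cell line, 3 treated with DMSO and 3 with H3B-8800 for 24 h, and groups and replicate numbers were taken from the sample titles. Per the labels' protocols, RNA was selected with oligo-dT beads, libraries were made with the strand-marking dUTP method, and 50 bp single reads were sequenced on an Illumina NextSeq. The series' design text, which covers several experiments, instead names an unstranded kit and paired-end reads. Which of these holds was not settled, so reads of genes that overlap on opposite strands, and of 1452 tested antisense genes (434 higher, 364 lower), are uncertain in origin.

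The authors deposited 1 table with CPM values per gene and library and the results of their own test. Per the submitters' processing notes, bcl2fastq, TopHat, HTSeq and edgeR were used, and the genome build was hg19, with no versions and no settings. The gene coordinates in the table go against that label. Of 15229 gene identifiers also present in GENCODE release 29 on GRCh38, 13941 (91.5%) had identical coordinates. Coordinates are printed as deposited and were read as GRCh38. Each deposited CPM column sums to between 997381 and 997786, so the authors set CPM against a read total taken before genes were left out. No further scaling factor shows in the values. Every gene in the deposited table has a CPM above 1 in at least 2 libraries. The deposited log2 fold changes and mean log2 CPM, the likelihood-ratio score and the p-values with their adjusted values come from the authors' edgeR fit, per the file headers. No column belonged to another sample.

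Every deposited CPM value was a whole multiple of what 1 read is worth in its library, within a tolerance of 0.01 of a read (100% of values). This gave the read total behind each library's CPM. The design fixed before the data were examined expected read counts and a count-based test, and named a fallback for normalized values. Because the table holds another unit, CPM, the fallback was used. Genes with a CPM of at least 1 in 3 or more libraries were kept (15188 genes, 229 removed), and log2(CPM + 0.5) was fitted with limma 3.58.1 in R 4.3.3, with an intensity trend and robust estimation, on all 6 libraries with the group as the single term. P-values were adjusted by the Benjamini-Hochberg method and called at 0.05. All adjusted p-values of single genes are from this limma fit unless the authors' deposited table is named. Across genes, which are not independent replicates, these log2 fold changes and the authors' correlated with a Pearson r of 0.98.

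Gene lists were fixed before the data were examined. The 27 lists with at least 5 tested members were compared with all other genes by camera with a preset inter-gene correlation of 0.01, adjusted over the lists. With an estimated correlation, none of the 11 calls held at an adjusted p of 0.05 (7 lists at an unadjusted p under 0.05), and those p-values stand beside each list. Genes named in the text are the 10 largest rises and 10 largest falls among called genes with a mean CPM of at least 10, groups that do not overlap and a proper symbol, 8 genes tied to the study, and for each list described the 2 members per direction with the smallest p-values. Results for 2 of these genes are left out because they are withheld for evaluation. Where a called or lead list had 5 or fewer exceptions, and for markers of other cell types, the remaining members are named too. Those names, and genes outside the rule in the closing section, were chosen after their values were seen. Of the gene identifiers, 457 had no symbol in the table.

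Alternatives covered other scalings, pseudocounts and filters, a replicate block, leaving out each library, the authors' table and other set tests. Added after the data were seen were the removal of each library's trend on transcript GC content and length (a spline with 5 degrees of freedom), limma without trend and robust estimation, and protein-coding genes alone. No pair of replicates was close enough to be the same library, since all pairs differed beyond sampling noise. The fit was tested on simulated data made from these libraries' means, with 15054 genes fitted. It called 76% of 50 genes changed 1.25-fold and 100% of 50 genes at each of 1.5-fold, 2-fold and 4-fold. A further set of genes was shifted to test camera and is not in these shares. Of 14814 unchanged genes 13 were called, which made up 5.46% of the calls. The simulation changed few genes, with independent noise and no GC trend, whereas 10297 genes were called in the real data. These rates therefore need not hold for the real calls. Splicing itself was not analysed here, since the table holds a single value per gene.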

Results

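RNA from Jurkat cells, an established human T cell acute lymphoblastic leukaemia line grown in suspension, was sequenced after 24 h with the compound H3B-8800 or with DMSO as the control. H3B-8800 is a small-molecule modulator of SF3b, the complex of the U2 snRNP that recognises the branch point of an intron. The labels give no dose. Each group held 3 libraries, numbered 1 to 3 in both groups. The deposited table gave depth-normalised read counts (CPM) for 15417 genes. These genes took up 99.7% to 99.8% of the read total on which each library's CPM was based. That total, worked out from the CPM values, was 70750759, 56399335 and 77651410 reads for DMSO replicates 1, 2 and 3. For H3B-8800 replicates 1, 2 and 3 it was 81057284, 84073796 and 65369817 reads. Reads assigned to no gene may be left out of it, so it need not be the number of reads sequenced. At this depth 3 reads, the floor used here for a single library, equal between 0.0357 and 0.0532 CPM. Intervals and floors of this kind cover counting error only. Nothing in the labels says whether the libraries came from separate cultures, and the series' description speaks of biological or technical replicates, so p-values measure only the spread between these samples, which may be technical.

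The comparison asked which genes change in RNA level when SF3b is modulated in a T cell leukaemia line. Genes of mitosis, DNA replication, cholesterol synthesis and endoplasmic reticulum chaperones were lower after H3B-8800, and interferon-stimulated genes and ribosomal protein genes were higher. The recombinase genes RAG1 and RAG2 showed the largest falls among called genes at 10 CPM or more with a proper symbol and groups that do not overlap. The results for groups of genes are calls of camera with a preset correlation between genes, and none of them held at an adjusted p of 0.05 with an estimated correlation (7 lists at an unadjusted p under 0.05). The preset test called 11 lists here. It called 6 to 13 in the 9 other splits of the 6 libraries into 3 against 3, where limma called 0 genes. Those splits mix both groups on each side, so part of any treatment effect stays in them. Of 15188 genes tested with limma, 10297 passed an adjusted p of 0.05, with 5678 higher and 4619 lower. Most of these changes were small, with a median absolute log2 fold change of 0.32 among the genes called. Changes of 2-fold or more numbered 431, of which 238 were higher and 193 lower. The libraries of the groups did not overlap for 70.6% of the genes tested, against 10% by chance for 3 against 3. Fold changes are on the log2(CPM + 0.5) scale, which understates the change of low genes. In the authors' deposited table, 5248 genes were higher and 5189 lower at the same threshold, and 733 changed by 2-fold or more.

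CMYA5 encodes a muscle sarcomere and costamere protein. It had the largest rise among called genes at 10 CPM or more with a proper symbol and groups that do not overlap. CMYA5 (ENSG00000164309, chromosome 5, 79689877 to 79800240) went from 2.04 ± 0.151 to 30.2 ± 3.14 CPM (SD, n = 3 each). Its log2 fold change was 3.59 with an SE of 0.0761 (limma adjusted p = 1.06e-15). Both mitochondrial ribosomal RNAs rose. MT-RNR1, the small-subunit rRNA (mitochondrial genome, 648 to 1601), went from 456 ± 9.2 to 1704 ± 44.7 CPM, and MT-RNR2, the large-subunit rRNA (1671 to 3229), went from 1695 ± 42.5 to 5352 ± 200.2 CPM. These are rises of 3.74-fold and 3.16-fold, while of 13 mitochondrially encoded mRNAs 2 passed the threshold, by 1.15-fold and 1.13-fold. Copies of mitochondrial sequence in the nuclear genome make the count of such reads uncertain. KRT1, a keratin, rose 3.49-fold, ID3, an inhibitor of basic helix-loop-helix transcription factors, 2.72-fold, and CHD5, a chromatin remodeller, 3.14-fold. KIAA1024 rose 2.68-fold from 22.8 ± 0.588 to 61.98 ± 2.95 CPM. The leptin receptor gene LEPR rose 4.49-fold, the aminopeptidase-like gene NPEPL1 3.5-fold and AHRR, the repressor of the aryl hydrocarbon receptor, 2.69-fold. These 3 genes share exons on the same strand with LEPROT, STX16-NPEPL1 and PDCD6, and CHD5 does with AL031847.2, so the reads of all 4 are uncertain in origin.

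RAG1 and RAG2, which encode the recombinase that assembles antigen receptor genes, fell furthest among genes selected in the same way. RAG1 (ENSG00000166349, chromosome 11, 36510709 to 36593156) dropped from 52.5 ± 1.85 to 8.54 ± 0.357 CPM, a fall of 5.87-fold (log2 fold change -2.55, SE 0.0501, limma adjusted p = 3.82e-16). RAG2 (ENSG00000175097, chromosome 11, 36575574 to 36598279) dropped from 19.8 ± 0.757 to 3.97 ± 0.411 CPM, a fall of 4.54-fold. The annotations of this pair overlap on opposite strands, and the labels disagree on whether the libraries kept strand. CDC40, a splicing factor that acts at the second catalytic step, fell 3.1-fold from 75.7 ± 1.7 to 24.1 ± 0.494 CPM (ENSG00000168438, chromosome 6, 110180141 to 110254275). CDKN3, a phosphatase of cyclin-dependent kinases, fell 2.97-fold. The amino acid transporter gene SLC16A10 fell 3.6-fold, the sphingolipid transporter homologue SPNS3 3.05-fold and ZBED6CL 3.13-fold. ZNF587B, C22orf39 and CHML fell 3.81-fold, 3.42-fold and 3.35-fold, and each shares exons on the same strand with a neighbour (ZNF586, HIRA and OPN3). The 20 genes of this and the preceding paragraph were selected for groups that do not overlap.

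**Figure D1:**
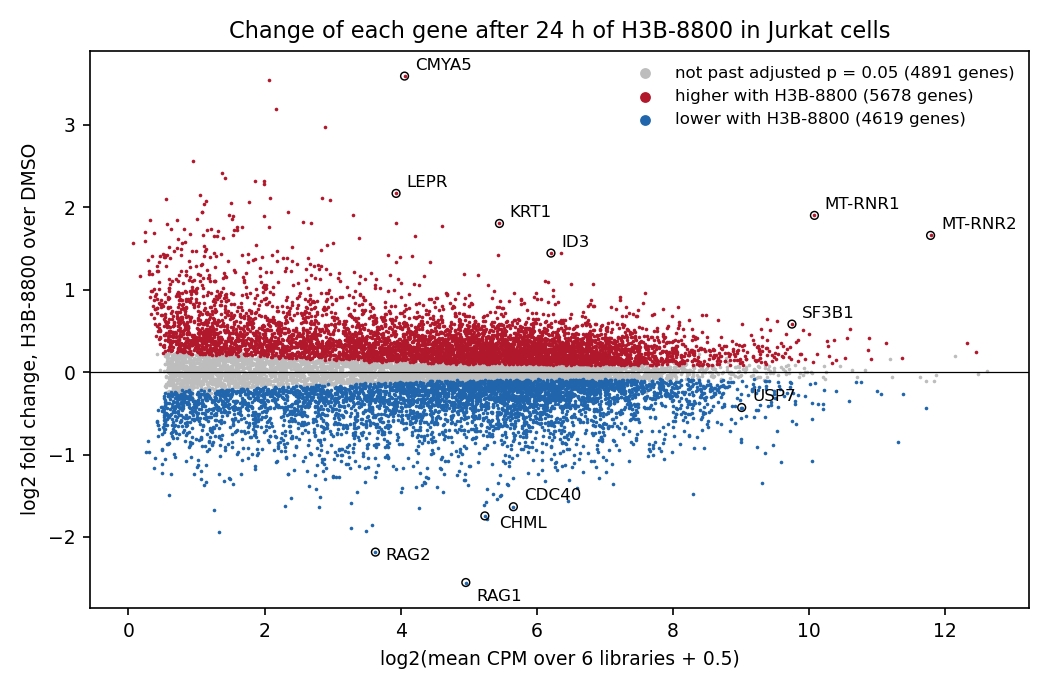
Each point is 1 of 15188 genes, with log2 of mean CPM plus 0.5 on the x axis and the log2 fold change of H3B-8800 over DMSO on the y axis. Red and blue mark the 5678 genes higher and the 4619 genes lower at an adjusted p of 0.05, most of them close to 0, with CMYA5 at 3.59 and RAG1 at -2.55 at the edges.

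Genes listed beforehand for their tie to the study, 7 of which are given here, changed by less. SF3B1, the SF3b subunit at the compound's binding site, rose 1.5-fold from 687 ± 7.61 to 1029.7 ± 22.5 CPM (ENSG00000115524, chromosome 2, 197389784 to 197435091, limma adjusted p = 1.63e-10). SRSF6, an SR protein that regulates exon inclusion, fell 1.24-fold from 373 ± 5.88 to 301 ± 10.04 CPM. USP7, a deubiquitinase, fell 1.35-fold from 591 ± 7.59 to 439 ± 14.7 CPM, and the proteasome assembly chaperone gene PSMG1 fell 1.31-fold. The oncogene MYC fell 1.43-fold from 326 ± 12.6 to 228 ± 1.16 CPM (limma adjusted p = 2.08e-09). MCL1, an anti-apoptotic BCL2 family member, stood at 176 ± 0.868 CPM under DMSO and 168 ± 3.37 CPM after H3B-8800 (SD, n = 3 each), and its log2 fold change of -0.07 did not pass the test (limma adjusted p = 0.109). NOTCH1, the receptor often mutated in this leukaemia, had a log2 fold change of 0.17 (limma adjusted p = 0.0476), and its groups overlapped. This call was lost when any 1 library other than H3B-8800 replicate 2 was left out (adjusted p = 0.0764 to 0.199, log2 fold change 0.11 to 0.2), and without that library the adjusted p was 7.41e-07 (log2 fold change 0.26). With the replicate number as a block in limma the call held (adjusted p = 0.0117). In settings chosen after the data were seen it was also lost, with GC and length trends removed (log2 fold change 0.02, adjusted p = 0.621) and in limma without an intensity trend or robust fit (adjusted p = 0.0903, with the log2 fold change of the main fit). MCL1 passed the test when that library was left out (adjusted p = 0.0261), with scaling by median of ratios (adjusted p = 0.033) and in the authors' deposited table (adjusted p = 0.0206).

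Of the 27 lists tested, G2/M and mitosis had the largest share of members called in one direction, although other lists had a smaller spread of fold changes. Of 49 tested genes of the G2 phase and mitosis, 48 fell and none rose by limma, with a median log2 fold change of -0.87. The counts were the same adjusted over the list alone, at an unadjusted p under 0.05 and in the authors' deposited table, and the remaining gene was CDC25B. TOP2A, the topoisomerase that separates sister chromatids, fell 2.54-fold from 905 ± 2.27 to 357 ± 10.4 CPM, and the spindle checkpoint kinase gene BUB1B fell 2.16-fold, although it shares exons with the read-through gene BUB1B-PAK6. The list was lower than other genes by camera (adjusted p = 4.13e-26 with the preset correlation, adjusted p = 0.139 with an estimated correlation). Among 43 tested genes of the G1/S step and DNA replication, 38 fell and 1 rose (median log2 fold change -0.36; the same counts adjusted over the list alone). CDC45, part of the replicative helicase, fell 2.21-fold, and E2F8, a repressor of the E2F family, fell 2.12-fold. The exception was CCND2, which encodes cyclin D2 and rose 2.9-fold from 3.37 ± 0.203 to 10.7 ± 0.516 CPM. Camera gave an adjusted p = 5.52e-12 for this list, and an adjusted p = 0.139 with an estimated correlation. Of 42 genes of homologous recombination, the Fanconi pathway and replication checkpoints, 29 fell and 7 rose, also over the list alone (median -0.31). FANCI fell 1.72-fold and the checkpoint kinase gene CHEK2 1.73-fold, while RAD50, of the complex that senses double-strand breaks, rose 1.47-fold (camera adjusted p = 2.15e-05; adjusted p = 0.139 with an estimated correlation). Only 1 of 29 replication-dependent histone genes could be tested, HIST3H2A, and it did not pass the threshold (limma adjusted p = 0.0997), so that list was not tested as a set.

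Lipid, chaperone and metabolic lists were lower too. Of 25 genes of cholesterol synthesis and uptake, 21 fell and none rose by limma (22 and none adjusted over the list alone or at an unadjusted p under 0.05, 23 and none in the authors' deposited table), with a median log2 fold change of -0.46. HMGCS1, an early enzyme of the mevalonate pathway, fell 1.82-fold from 356 ± 10.5 to 195 ± 6.13 CPM, and FDPS, which makes farnesyl diphosphate, fell 1.8-fold (camera adjusted p = 9.78e-09; adjusted p = 0.0663 with an estimated correlation). In the unfolded protein response and chaperone list, 19 of 23 genes fell and 1 rose, also over the list alone (median -0.28). The endoplasmic reticulum chaperone genes HSPA5 and HSP90B1 fell 1.89-fold and 1.98-fold, and SYVN1, a ubiquitin ligase of protein quality control, rose 1.2-fold (camera adjusted p = 2.00e-06; adjusted p = 0.16 with an estimated correlation). Targets of ATF4 in the integrated stress response fell in 24 of 36 cases and rose in 4, also over the list alone (median -0.21). SLC7A11, the cystine transporter, fell 2.07-fold and the transcription factor gene ATF5 1.87-fold, whereas PPP1R15A, a regulatory subunit of the phosphatase that reverses eIF2-alpha phosphorylation, rose 1.5-fold, and DDIT4 and the amino acid transporter genes SLC7A5 and SLC3A2 rose by 1.19-fold or less (camera adjusted p = 1.85e-04; adjusted p = 0.184 with an estimated correlation). Of 28 glycolysis and hypoxia genes, 17 fell and 4 rose (median -0.23), the same over the list alone. The glycolytic enzyme genes GPI and TPI1 fell 1.54-fold and 1.51-fold, and the glucose transporter gene SLC2A3, ALDOC, NDRG1 and KDM3A rose by between 1.26-fold and 1.65-fold (camera adjusted p = 0.0183; adjusted p = 0.562 with an estimated correlation). Proteasome subunits and assembly factors fell in 26 of 48 cases and rose in 7, also over the list alone (median -0.12), with PSME1, of an interferon-inducible proteasome activator, 1.58-fold lower and ADRM1, a ubiquitin receptor, 1.27-fold higher (camera adjusted p = 0.00407; adjusted p = 0.562 with an estimated correlation).

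**Figure D2:**
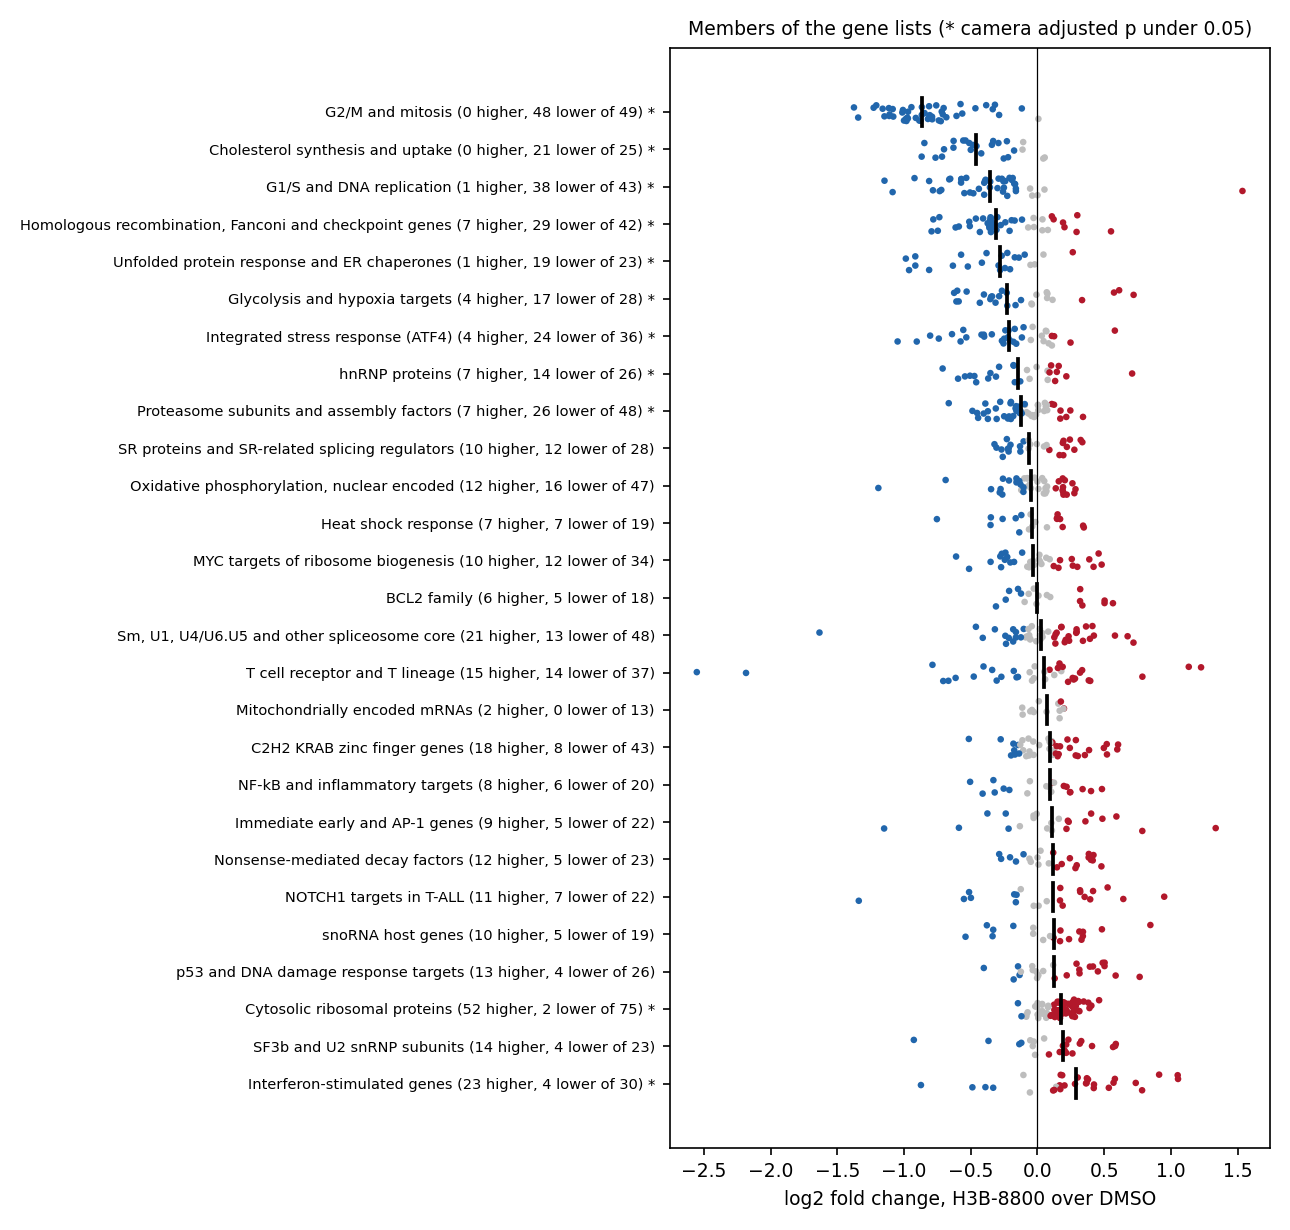
Each row is a gene list and each point a tested member, at its log2 fold change of H3B-8800 over DMSO, red where higher and blue where lower at an adjusted p of 0.05 and grey otherwise. Black bars mark list medians, which run from -0.87 for G2/M and mitosis to 0.29 for interferon-stimulated genes, and a star marks the 11 lists called by camera with the preset correlation.

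Genes of the splicing machinery moved both ways, as did the 15188 genes tested (5678 higher and 4619 lower). Of the 23 genes of SF3b and the U2 snRNP, 14 rose and 4 fell, also over the list alone (median 0.19), and the list was not called (camera adjusted p = 0.137). SF3B3 rose 1.5-fold from 411 ± 14.9 to 618 ± 8.93 CPM, close to the 1.5-fold of SF3B1, while the helicase gene DDX46 fell 1.9-fold from 291 ± 5.61 to 153 ± 3.09 CPM, with exons that overlap C5orf24. U2SURP, SF3B5 and DDX42 also fell, by 1.29-fold, 1.1-fold and 1.09-fold. Members of the hnRNP list fell in 14 and rose in 7 of 26 cases, also over the list alone (median -0.15). HNRNPDL and HNRNPH1 fell 1.64-fold and 1.51-fold, and PTBP2, a splicing repressor best known in neurons, rose 1.64-fold. Camera called the hnRNP list (adjusted p = 0.033; adjusted p = 0.783 with an estimated correlation), but not without DMSO replicate 3 (adjusted p = 0.0535) or without H3B-8800 replicate 3 (adjusted p = 0.0563). SR proteins and their regulators split into 10 higher and 12 lower of 28, also over the list alone, with the kinase gene SRPK2 1.26-fold higher and SRSF7 1.21-fold lower (camera adjusted p = 0.606). In the remaining spliceosome core, 21 rose and 13 fell of 48, again the same over the list alone (camera adjusted p = 0.606). There the helicase gene DHX38 rose 1.65-fold and PRPF6, of the U5 snRNP, 1.6-fold, and CDC40 was the single member to change by 2-fold or more. Nonsense-mediated decay factors rose in 12 and fell in 5 of 23 cases, also over the list alone, led by UPF3B at 1.39-fold (camera adjusted p = 0.17). Of 19 snoRNA host genes, 10 rose and 5 fell, also over the list alone, with ZFAS1 1.8-fold higher and DANCR 1.45-fold lower (camera adjusted p = 0.433).

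Interferon-stimulated genes rose in 23 and fell in 4 of 30 cases, also over the list alone, with a median log2 fold change of 0.29. IFIT2, a translation inhibitor of the antiviral response, rose 2.07-fold from 7.53 ± 0.206 to 16.1 ± 0.38 CPM, and XAF1, a pro-apoptotic antagonist of XIAP, rose 1.88-fold from 103 ± 2.6 to 194 ± 6.04 CPM. The 4 that fell were IFI35, OAS3, IFI6 and USP18, by 1.83-fold, 1.4-fold, 1.31-fold and 1.26-fold (camera adjusted p = 0.00407 for the list; adjusted p = 0.139 with an estimated correlation). Cytosolic ribosomal protein genes rose in 52 and fell in 2 of 75 cases (53 and 2 adjusted over the list alone), by a small median log2 fold change of 0.18. RPL13A rose 1.38-fold, and the 2 that fell, RPLP0 and RPS2, changed by 1.11-fold and 1.09-fold (camera adjusted p = 2.36e-05; adjusted p = 0.562 with an estimated correlation). Ribosomal protein genes have many near-identical pseudogenes, so the reads of single members are uncertain.

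Lists of T cell and oncogenic programmes held both genes that rose and genes that fell, as did the genes tested as a whole. Of 37 genes of the T cell receptor and T lineage, 15 rose and 14 fell, also over the list alone (median 0.05, mean -0.09, camera direction lower with an adjusted p = 0.606, so median and test differ in sign). Besides RAG1 and RAG2, CD247, the zeta chain of the receptor complex, rose 1.32-fold from 111 ± 1.51 to 147 ± 2.43 CPM, and LMO2, a T cell oncogene, rose 2.34-fold from a low level of 0.582 CPM. NOTCH1 targets rose in 11 and fell in 7 of 22 cases, also over the list alone (camera adjusted p = 0.606). HES1, a direct target, rose 1.56-fold and RUNX1 1.44-fold, while NOTCH3 fell 2.53-fold from 28.6 ± 0.757 to 11.1 ± 1.19 CPM. MYC targets of ribosome biogenesis split into 10 higher and 12 lower of 34, also over the list alone, with the nucleolar protein gene NOP56 1.53-fold lower and PES1 1.4-fold higher (camera adjusted p = 0.606). Targets of p53 rose in 13 and fell in 4 of 26 cases, also over the list alone (camera adjusted p = 0.13), with TP53INP1, a stress-induced p53 cofactor, 1.7-fold higher and SESN2, a stress-induced inhibitor of mTORC1, 1.32-fold lower. In the BCL2 family 6 genes rose and 5 fell of 18, also over the list alone, with the pro-apoptotic genes BAX and BMF 1.42-fold and 1.48-fold higher and BIK and BCL2L11 1.24-fold and 1.18-fold lower (camera adjusted p = 0.789).

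**Figure D3:**
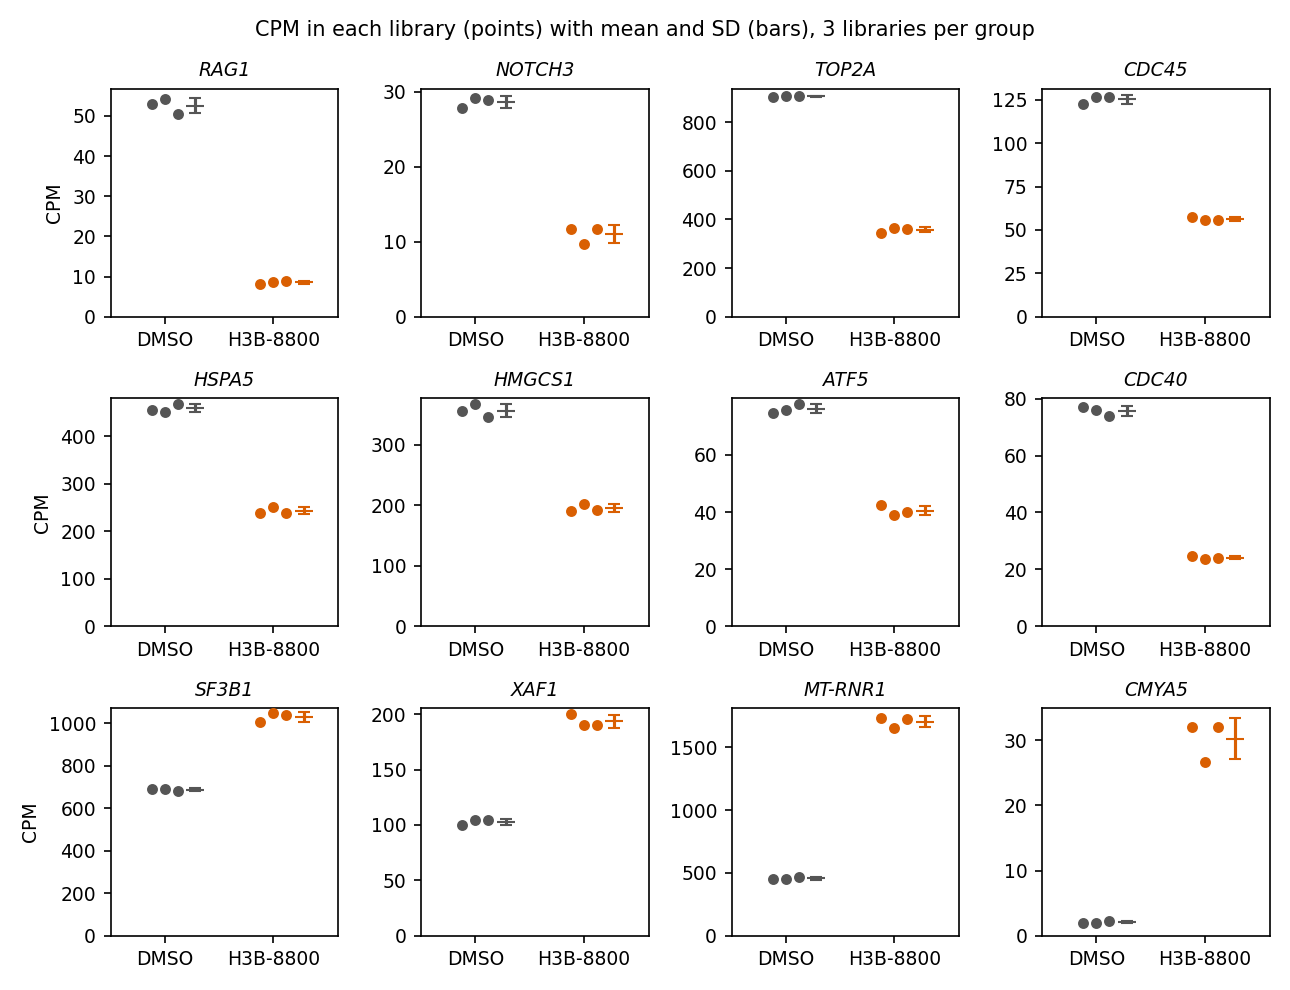
Points are CPM in the 3 libraries of each group for 12 of the genes named, and each bar is the mean with its SD on a linear axis that starts at 0. In all 12 genes the groups do not overlap, as for RAG1, near 52.5 CPM under DMSO and 8.54 CPM after H3B-8800. These genes had been selected for such groups or for the smallest p-values in a list, so this is no separate result.

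The other lists were not called. Heat shock genes split evenly at 7 higher and 7 lower of 19 (CHORDC1, a co-chaperone of HSP90, 1.69-fold lower; camera adjusted p = 0.607). Immediate early genes rose in 9 and fell in 5 of 22 cases, with KLF2, a quiescence factor of T cells, 2.52-fold higher and EGR1 2.22-fold lower (camera adjusted p = 0.45). NF-kB targets rose in 8 and fell in 6 of 20 cases, with the subunit gene RELA 1.4-fold higher and CD83 1.33-fold lower (camera adjusted p = 0.769). Nuclear genes of oxidative phosphorylation rose in 12 and fell in 16 of 47 cases (15 adjusted over the list alone), and NDUFA10, of complex I, fell 2.28-fold from 109 ± 2.75 to 47.4 ± 1.03 CPM (camera adjusted p = 0.446). KRAB zinc finger genes rose in 18 and fell in 8 of 43 cases (camera adjusted p = 0.328). The 2 mitochondrial mRNAs that rose were MT-ND3 and MT-CYB, and their list was not called (camera adjusted p = 0.735). Adjusted over the list alone, 1 mitochondrial mRNA passed, and the counts of the heat shock, immediate early, NF-kB and zinc finger lists did not change. The MT-CYB call (limma adjusted p = 0.0403) was lost without any 1 of DMSO replicates 2 and 3 and H3B-8800 replicates 1 and 3 (adjusted p = 0.0906 to 0.135), with a log2 fold change of 0.11 without H3B-8800 replicate 1, 0.12 without DMSO replicate 2, and 0.17 and 0.18 without H3B-8800 replicate 3 and DMSO replicate 3. It was also lost with scaling by median of ratios (adjusted p = 0.0527) and in the authors' deposited table (adjusted p = 0.0655), each with a log2 fold change of 0.14. With the replicate block in limma the call held (adjusted p = 5.38e-04). In settings chosen after the data were seen it was lost with GC and length trends removed (log2 fold change 0.23, adjusted p = 0.0856) and in limma without an intensity trend or robust fit (adjusted p = 0.0788, with the log2 fold change of 0.18 as in the main fit), so in these 2 settings the change was not smaller but less precise. Same-strand exons are shared with another annotated gene, in some cases a small RNA inside the gene, by further genes named in this text: ATF5, CCND2, GPI, HSP90B1, IFIT2, MCL1, NOP56, RAD50, RPL13A, RPS2, SYVN1, U2SURP and ZFAS1.

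Few markers of cell types other than T cells were measurable. The table listed 3 of 12 B cell, 1 of 14 myeloid, 1 of 14 erythroid and megakaryocytic, and 3 of 15 fibroblast and epithelial markers. These were CD79A, EBF1 and BLNK, then CEBPA, then ITGA2B, then COL1A1, FN1 and THY1, and CD79A and THY1 had most of the reads. Of these 8 genes, BLNK changed most, from 0.355 to 1.19 CPM, and COL1A1 alone fell. The summed levels of the markers were 18.5 ± 0.521 and 21.6 ± 1.06 CPM for B cell markers under DMSO and H3B-8800, and 45.8 ± 1.69 and 49.8 ± 1.58 CPM for fibroblast and epithelial markers (SD, n = 3). For myeloid markers they were 4.32 ± 0.244 and 4.97 ± 0.18 CPM, and for erythroid markers 1.14 ± 0.13 and 1.55 ± 0.192 CPM. Within the treated group, replicate 2 stood apart from the rest. Its read counts differed from those of replicates 1 and 3 with a chi-square per degree of freedom of 19.9 and 14.4, against 4.02 between replicates 1 and 3 and 5.15 to 7.16 among the DMSO libraries, and a value of 1 is expected from sampling alone. Without that library, 6048 genes were higher and 4713 lower, and 11 lists were called, as with it.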

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

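Removing GC and length trends, protein-coding genes alone and limma without trend were chosen after the data were seen. The count-based tests that were planned were not run: the table's unit is CPM, for which the design named the limma fit, although whole reads could be worked out from it; total-count scaling and the CPM filter are the setting used. The number of genes called stayed within 1.5 times of 10297 in every setting, from 8501 (protein-coding genes alone, fewer tested) to 11199 (GC and length trends removed), and leaving out 1 library gave 9437 to 10761. The 2-fold count was 415 to 475 leaving out 1 library. It was 624 (361 higher, 263 lower) with a pseudocount of 0.1, which shrinks low genes less, 312 (163 higher, 149 lower) with a pseudocount of 1, and 733 (402 higher, 331 lower) in the authors' deposited table, where the cause was not tested. Median-of-ratios scaling moved the median of all genes from 0.04 to 0.00 on the log2 scale and the share of calls that were higher from 55.1% to 49.6%. The series' design text names matched treatment and control pairs but no model for them. Across genes, deviations of same-numbered libraries did not correlate (-0.23, -0.07 and -0.02), and no library correlated best with its own number. GC trends in some libraries may hide a pairing, so this cannot show that the samples were unpaired. The mitochondrially encoded share, looked at afterwards, ranked replicates 1, 3 and 2 in both groups (3.81%, 3.34% and 3.27% under DMSO, 4.37%, 4.12% and 3.63% after H3B-8800). With the replicate block 10047 genes were called, 431 by 2-fold or more.

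Camera called 11 lists, 10 to 11 leaving out 1 library. With an estimated correlation it called 0 (0 higher, 0 lower; 7 at an unadjusted p under 0.05), a test with 4 residual degrees of freedom; fry called 23, 12 of them higher, and fry does not compare a list with other genes. Over 16 alternatives, 120 named genes gave 1914 values, of which 1896 kept their direction and side of the threshold, 15 lost the call (NOTCH1 in 7 settings, MT-CYB in 8) and 3 gained it (MCL1). NOTCH1 had a log2 fold change of 0.02 once GC and length trends were removed (adjusted p = 0.621; range over alternatives 7.41e-07 to 0.621). None reversed. Of 459 list values, 434 kept theirs, 13 lost and 12 gained the call. Depth limits little, since genes near 1 CPM lie far above 3 reads (at most 0.0532 CPM).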

Other observations

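The genes in this part outside the rule were chosen after their values were seen, as were the tests on mitochondrial rRNA, on a weaker response of H3B-8800 replicate 2, on scaling for the mitotic genes and on antigen presentation. The large rises were mostly in genes of low level and the large falls in genes of higher level. Of the 238 genes higher by 2-fold or more, 202 had a mean under 10 CPM, and of the 193 lower ones 78 did, which leaves 36 higher and 115 lower at 10 CPM or more. The natriuretic peptide receptor gene NPR3 went from 0.16 ± 0.0564 to 7.17 ± 0.432 CPM, and GNA14, a G protein subunit gene, from 0.384 ± 0.0799 to 7.57 ± 0.723 CPM (SD, n = 3 each). SDCBP2 went from 1.17 ± 0.0806 to 12.7 ± 0.282 CPM, with exons that overlap AL136531.2. Among low genes that fell, MFAP4, which encodes a protein of the extracellular matrix, went from 13.98 ± 0.733 to 4.32 ± 0.52 CPM. ID1, a relative of ID3, rose 2.18-fold from 9.29 ± 0.295 to 20.9 ± 0.926 CPM. One pseudogene, HMGN1P13 (chromosome 5, 111572102 to 111572239), had 0 reads in all 3 DMSO libraries and 1.06 ± 0.194 CPM after H3B-8800, at least 20-fold higher than 3 reads in the shallowest control library, although its reads are uncertain because of its parent gene.

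Some genes with large changes share exons with a neighbour that moved the other way, and others with 1 that moved the same way. LEPR rose by 2.17 on the log2 scale while LEPROT, which shares its first exons, had a log2 fold change of -0.71. AHRR rose by 1.43 beside -0.31 for PDCD6, and CHML had -1.74 beside 0.38 for OPN3. ZNF587B and ZNF586 went the same way (-1.93 and -1.46), as did C22orf39 and HIRA (-1.78 and -0.20). NPEPL1 and the read-through gene STX16-NPEPL1, with which it shares exons, both rose (1.81 and 1.48), while STX16, which shares exons with the read-through gene and not with NPEPL1, had -0.79. Genes that share exons on the same strand with another gene made up 23.4% of the genes changed 2-fold or more (101 genes), against 15.9% of the genes tested (Fisher's exact test, two-sided, p = 4.14e-05, across genes, which are not independent).

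Both mitochondrial rRNAs rose by over 3-fold while mitochondrial mRNAs hardly moved. Weaker poly-A selection of the treated libraries would raise other RNAs without a poly-A tail by a similar factor, but 19 such RNAs, all above the 3-read floor, had a median log2 fold change of 0.136 (SD 0.349), below the 1 set for that explanation. By limma 5 of the 19 were higher and 0 lower (6 and 0 at an unadjusted p under 0.05, 5 and 1 in the authors' deposited table). The largest rise, of SNORD19 from 0.793 to 1.87 CPM, was 1.84-fold on the log2(CPM + 0.5) scale, which understates low genes. All 19 were low, at 0.512 to 7.94 CPM under DMSO, against 456 and 1695 CPM for the rRNAs. They include snoRNAs and copies of small RNAs, whose reads may come from host or parent genes. They are thus a weak gauge of poly-A selection, and a shift of this kind, smaller or similar, is not excluded. More mitochondrial RNA of every kind is argued against by the 13 mitochondrial mRNAs (median log2 fold change 0.0692, SD 0.121). Of 6 mitochondrial tRNAs tested, MT-TP, MT-TY and MT-TQ were higher, by 1.29-fold, 1.29-fold and 1.19-fold, far less than the rRNAs. A change in the amount of these rRNAs after H3B-8800, or in the tails by which they are captured, may remain and was not tested.

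H3B-8800 replicate 2 lay apart from replicates 1 and 3, with an SD of its deviations across genes of 0.134 (log2), against 0.1 and 0.0975 for the deviations of replicates 1 and 3. Across genes, its deviation followed transcript GC content (Spearman rho -0.542), and not exonic length (rho 0.0148), so a GC trend of library preparation is a candidate explanation. The rho was 0.52 for replicate 1 and 0.224 for replicate 3. These deviations are each taken from the other 2 treated libraries and so are bound to each other, and which library holds the trend cannot be told from them. In the other group, DMSO replicate 1 had a rho of -0.396 against the other 2 DMSO libraries. Removing GC and length trends left an SD of 0.112 for replicate 2, against 0.0882 and 0.091 for replicates 1 and 3. A weaker response to the compound cannot be told apart from this, since the slope of its changes relative to the other treated libraries was 0.926 (range 0.907 to 0.938), between the bounds set for and against it. After the trends were removed it was 0.958 (range 0.948 to 0.97), which meets the bound set against a weaker response (0.95 or more), apart from the low end of its range.

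The fall of the mitotic genes could arise from a GC or length trend, or from the scaling. After removal of the trends the median log2 fold change of the 49 genes was -0.841. Its bootstrap SE of 0.0379 is across genes, which are not independent, and does not measure the spread between libraries. Under the other 2 scalings the median was -0.865 or lower, against -0.87 as reported, so neither the trends nor the scaling accounts for the fall. A hypothesis is that fewer cells were in or near mitosis at 24 h, but no cell cycle measurement was analysed here and lower RNA per cell stays open.

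If splicing failure lowered RNA in proportion to introns, genes with more exons would fall more. Across 12017 protein-coding genes, which are not independent, the Spearman rho of log2 fold change with exon number was 0.0303 (permutation p = 0.002, two-sided, 2000 permutations). This is in the opposite direction, so no loss in proportion to exon number was seen. The rho was -0.00827 after GC and length trends were removed. Exon number itself follows length (rho 0.557), so that removal can take out an exon trend and does not decide the question. CPM values are relative, so a loss shared by nearly all genes could not show. The 184 single-exon genes had a median 0.0473 above the others (bootstrap SE 0.028, permutation p = 0.0933, two-sided, both across genes). After GC and length trends were removed it was 0.0562 above. This is too imprecise to say whether they stand above. Of the single-exon genes 18.5% were lower, against 28.5% to 34.6% in the bins of genes with more exons, a difference that was not tested. The share that was higher, 41.3%, lay within the 30.6% to 42.2% of those bins. A list of MHC class I and antigen presentation genes did not rise together: 8 rose and 8 fell of 18 (camera p = 0.97 with the preset correlation, unadjusted).

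The 6 libraries can be split 3 against 3 in 10 ways, too few for a share under 0.05. The real split called 10297 genes, 431 of them by 2-fold or more, and the highest of the other splits called 0 of either by limma, with 2 to 158 genes at an unadjusted p under 0.05 against 10657 for the real split. For gene lists, the real split gave 11 and the highest other 13, and 3 of the 10 splits, the real one included, gave 11 or more. Each of the other splits holds 2 libraries of 1 group and 1 of the other on each side, so part of any treatment effect stays in them, and their counts do not show what chance alone would give.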
